A study of Glycine max with 18 samples.

How the data were processed

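Root messenger RNA was measured in 18 libraries of soybean (Glycine max), 3 from each of 6 groups. The groups were roots of line Gm072 and of line Gm137, each infected with race 3 of the soybean cyst nematode Heterodera glycines, infected with race 2, or left noninfected. Per the labels' protocols, total RNA was extracted with hot phenol and polyadenylated RNA was made into libraries for paired-end sequencing. The labels call the replicates biological, but do not say how many plants went into one library or when roots were sampled. P-values therefore measure the spread between these libraries. The labels do not say which line is resistant to which race, and no such status was assumed.

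The deposited values are raw read counts per gene, one column per library, with no normalization and no pooling of replicates. Per the submitters' processing notes, Trimmomatic, STAR, HTSeq and DESeq2 were used; versions, settings, genome build, annotation and strand setting are not given in the sources used here. The table held 52872 gene IDs of the Glyma kind and 5 HTSeq summary rows, of which the rows for low alignment quality and for unaligned reads were 0 in all 18 libraries. The summary rows stayed out of library sizes and tests. They made up between 5.47% and 10.2% of the table total, and the row for reads without a unique alignment made up between 3.41% and 7.11%. Reads that align to several places were left out of the gene counts, so counts of near-identical gene copies are uncertain. With the strand setting not given, overlapping genes on opposite strands are uncertain too.

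Gene counts summed to between 62.9 and 96.3 M reads per library. A count of 0 allows up to 3 reads. Where a whole group had no reads, a fold is given as a lower bound against 3 reads over the 3 libraries of that group. Intervals and bounds of this kind cover counting error only, and reads were not tagged with molecular identifiers as far as the labels say.

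Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr on the 6 groups, which left 41319 genes. Libraries were scaled with TMM factors, and a quasi-likelihood model (glmQLFit, robust) with 1 coefficient per group and no block was fitted to all 18 libraries together, so that the groups share an estimate of the spread. Each of 9 contrasts was tested with glmQLFTest. P-values were adjusted by the Benjamini-Hochberg method within a contrast, and a gene was called at an adjusted p under 0.05. The contrasts were the 4 infections against the noninfected roots of the same line, race 2 against race 3 within each line, the noninfected lines against each other, and the difference between the lines in the response to each race. Values named CPM are counts scaled by 1e6 over the library size with TMM scaling, computed here, and are given as mean ± SD over 3 libraries. Log2 fold changes use a prior count of 0.125. The standard error (SE) given with them is the absolute log2 fold change divided by the square root of the F statistic of the test. It is therefore approximate, most of all where a group has no reads.

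The deposited table does not pair gene IDs with names. The reference table of Glycine_max_v4.0 gives symbols but matched 0 of the 52872 IDs, so top-ranked genes outside the lists are printed by ID only. Gene lists were fixed before the data were examined. Of 27 lists, 22 were defined by gene descriptions and could not be filled without them, so they were not tested. The other 5 were defined by 44 published Glyma IDs, each entered together with its gene name as background knowledge. They cover nematode resistance loci, isoflavonoid and glyceollin synthesis, entry into phenylpropanoid and lignin synthesis, pathogenesis-related proteins, and leghemoglobins as a nodule marker. The names below are those of the lists and were not checked by sequence. Of 40 IDs whose family has a symbol in the reference, 37 had a symbol of that family on the chromosome that the ID names. The count table held 42 of the 44 IDs and 37 passed the filter. The 4 leghemoglobin IDs had 18 reads in all 18 libraries together and were not tested.

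Lists were tested with camera in limma 3.58.1 on voom values, two-sided, with a preset correlation of 0.01 between genes. Their p-values were adjusted over the lists and the 4 infection contrasts together, and over the lists in each other contrast. Camera with an estimated correlation, the number of members called genome-wide and the number called when p-values were adjusted over the list alone stand beside it. Fry, which asks whether list members change and not whether they stand above other genes, was run too and is given with the dependence on processing.

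The rule for named genes, also fixed before the data were examined, took the 10 highest and 10 lowest log2 fold changes per contrast among called genes with a mean log2 CPM of at least 1 and no overlap between the libraries of both groups. Chance alone gives non-overlapping groups of 3 in 10% of genes. For the line differences it required responses of opposite sign or differing by at least 1 on the log2 scale. It added every resistance-locus gene and up to 4 members of each list with the smallest p among those called. The text names a subset of these from the top of each ranking, and names a listed gene that was not called only to complete the account of its list.

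Overlaps between contrasts that share controls were set beside 100 simulated draws of unchanged infected groups against the same controls. Alternatives were RLE and upper-quartile scaling, a weaker and a stricter count filter, DESeq2 1.42.0, limma voom with quality weights, a fit of only the groups compared, a fold threshold, the replicate number as a block, and leaving out each library in turn. Leaving out Gm072 race 2 replicate 3 from contrasts that do not use it was added after seeing the data. On simulated counts with 200 changed genes, the fit for Gm072 race 3 against noninfected, run on 40768 genes, recovered 83% of 4-fold and 30% of 2-fold changes with 3 false among 116 calls. It made 7 false among 119 calls for Gm137 race 2 against noninfected (40735 genes) and 9 false among 126 for the noninfected lines (40746 genes). The same step for the line difference in the race 3 response, run on 40751 genes, recovered 64% of 4-fold and 3% of 2-fold changes with 3 false among 70 calls. A random list of unchanged genes in these simulations had a camera p of 0.607 for the Gm072 race 3 comparison and 0.0215 for the line difference. Changed genes were not taken from those of low mean CPM, and each gene was drawn on its own with the spread fitted to the data. Recovery at low levels, and false calls where libraries shift in many genes together, are therefore not covered.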

Results

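Roots of 2 soybean lines, Gm072 and Gm137, were profiled by RNA sequencing after infection with race 3 or race 2 of the soybean cyst nematode, a sedentary root parasite that feeds from a syncytium formed inside the root, and without infection. Each of the 6 groups had 3 libraries. Gene counts ran from 76.1 to 91.2 M reads in noninfected Gm072, from 66.6 to 68.9 M under race 3 and from 62.9 to 90.1 M under race 2. In Gm137 they ran from 72.3 to 96.3 M in noninfected roots, from 77.5 to 86.9 M under race 3 and from 69.2 to 89.1 M under race 2. The title of the series states an interest in resistant and susceptible interactions with different nematode types.

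The leading principal component of log2 CPM held 33.1% of the variance and ordered the libraries by infection. Noninfected libraries scored between 92.2 and 114, race 3 libraries between -146 and -95.9, and race 2 libraries lay between them from -46.2 to 64.3. The next component held 14.8% and was set by 1 library, Gm072 race 2 replicate 3, at -238 against -27.9 to 39.5 for the other 17. The component after it held 10.96% and separated the lines, with Gm137 from -77.2 to -24.0 and Gm072 from 47.0 to 66.5, except that library, at -22.8 next to the Gm137 range. Correlations of log2 CPM within a group were between 0.946 and 0.978 except for this library, at 0.902 and 0.905 with the other 2 of its group. No pair of replicates agreed within sampling noise, so no 2 columns were repeat counts of 1 library. Whether the RNA samples were separate rests on the labels, since separate preparations of 1 RNA would differ beyond that noise too.

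**Figure D1:**
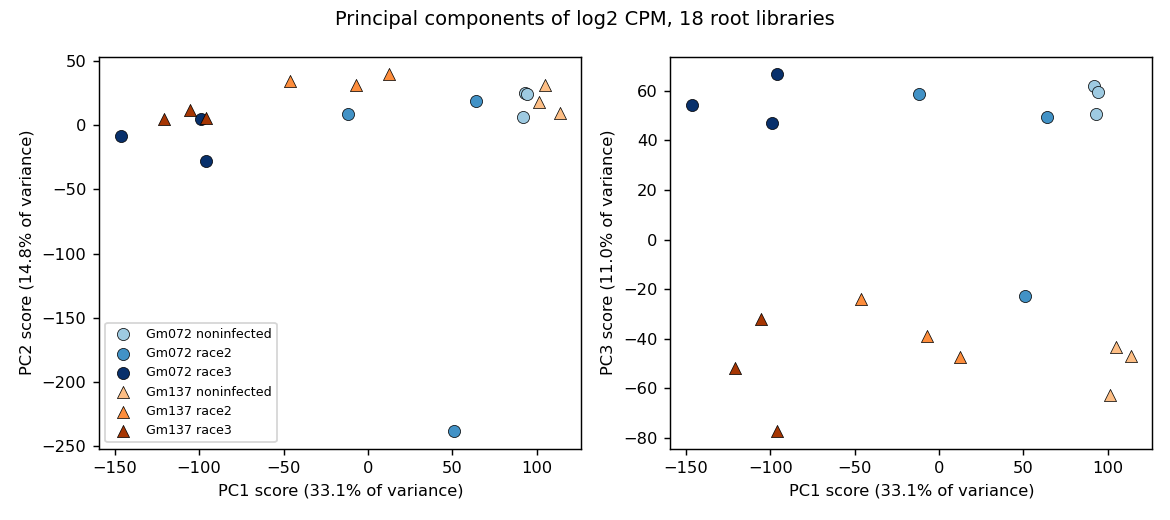
Scores of the 18 libraries on the first component against the next one (left) and against the one after it (right), in units of log2 CPM, with circles for Gm072, triangles for Gm137 and darker colours for infection. Noninfected libraries lie between 92.2 and 114 on the horizontal axis and race 3 libraries between -146 and -95.9, and Gm072 race 2 replicate 3 stands alone at -238 on the vertical axis of the left panel.

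Infection of Gm072 with race 3 raised genes of isoflavonoid synthesis together with pathogenesis-related genes. Of 14 tested genes of the isoflavonoid list, 11 rose, 1 fell and 2 did not pass the test, with a median log2 fold change of 2.37. G4DT (Glyma.10G295300), a prenyltransferase on the way to the soybean phytoalexins called glyceollins, went from 5.53 ± 2.96 to 231 ± 38.3 CPM (n = 3 each), a log2 fold change of 5.39 (SE 0.69, edgeR adjusted p = 8.92e-05). Chalcone synthase 7 (Glyma.01G228700), of the enzyme family that opens flavonoid synthesis, rose from 63.7 ± 13.4 to 633 ± 34.2 CPM, or by 3.31 (SE 0.32). Chalcone synthase 8 (Glyma.11G011500) rose by 2.42 (SE 0.27) and a chalcone reductase (Glyma.18G285800) by 2.90 (SE 0.33). A second chalcone reductase (Glyma.16G219400) went the other way, from 23.4 ± 2.20 to 11.02 ± 4.49 CPM, and fell by 1.09 on the log2 scale (SE 0.31). The list stood above other genes in camera (adjusted p = 1.46e-08), but not with an estimated correlation (adjusted p = 0.0857). Adjusted over the list alone, 12 members rose and 1 fell.

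The list for entry into phenylpropanoid synthesis was split in the same roots. Of its 11 tested members, 6 rose and 5 did not pass. Cinnamate 4-hydroxylase Glyma.20G114200 rose from 1.92 ± 0.703 to 58.5 ± 40.5 CPM, or by 4.93 (SE 0.69), and phenylalanine ammonia-lyase Glyma.03G181700 by 2.89 (SE 0.31). The most abundant ammonia-lyase, Glyma.10G058200, stood at 1658 ± 329 CPM without and 1652 ± 691 CPM with race 3. The camera call (adjusted p = 0.00334) was lost with an estimated correlation (adjusted p = 0.296), and 6 members rose and 1 fell when adjusted over the list alone. Of 4 tested pathogenesis-related genes, 3 rose. The PR10 gene SAM22 (Glyma.07G243500) went from 11.8 ± 0.386 to 880 ± 145 CPM, a log2 fold change of 6.22 (SE 0.71), and PR1 genes Glyma.15G062400 and Glyma.15G062500 rose by 5.31 (SE 0.53) and 4.08 (SE 0.48). The PR2 glucanase Glyma.03G132700 stood at 114 ± 41.7 CPM in noninfected and 15.5 ± 11.4 CPM in infected roots and did not pass the test (edgeR adjusted p = 0.133). Adjusted over this list alone, 3 members rose and 1 fell. The list was called by camera (adjusted p = 0.00146), but not with an estimated correlation (adjusted p = 0.145).

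Of the 8 tested resistance-locus genes 2 passed under race 3 in Gm072. The rhg1 alpha-SNAP gene (Glyma.18G022500), a vesicle-fusion protein, had a log2 fold change of 0.07 (SE 0.17), and the Rhg4 serine hydroxymethyltransferase (Glyma.08G108900) one of 0.14 (SE 0.19). The largest, GmSNAP02 (Glyma.02G260400), went from 0.493 ± 0.275 to 1.07 ± 0.283 CPM, or 1.12 (SE 0.77, edgeR adjusted p = 0.311), and did not pass. The rhg1 amino acid transporter (Glyma.18G022400) went from 681 ± 8.86 to 376 ± 134 CPM and fell by 0.86 (SE 0.30, edgeR adjusted p = 0.0476). It lost the call in 7 of 15 alternatives, RLE scaling and the removal of race 3 replicate 1 or 2 or any 1 noninfected library among them, with an adjusted p of up to 0.207 (without race 3 replicate 2). NSF (Glyma.07G195900), which disassembles SNARE complexes together with alpha-SNAP, rose by 0.54 (SE 0.15, edgeR adjusted p = 0.0171), with an adjusted p of up to 0.0965 (without race 3 replicate 2). Camera did not call the list (adjusted p = 0.706).

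In all, 10300 of 41319 genes were called in Gm072 under race 3, 5627 higher and 4673 lower, and 6061 of them changed at least 2-fold (edgeR, adjusted p under 0.05). Glyma.05G009000 ranked highest, with 8.12 ± 9.96 CPM under race 3 and no reads in noninfected roots, at least 695-fold higher against the floor of 3 reads over the group. Replicate 3 held 19.6 CPM of it and the other 2 held 2.79 and 1.97 CPM, and the bound was 203-fold without replicate 3. Among the genes that fell, Glyma.12G176200 ranked lowest, from 2.39 ± 0.908 to 0.00505 ± 0.00874 CPM, with race 3 reads in replicate 1 only. Glyma.13G323800 went from 5.89 ± 0.199 to 0.0755 ± 0.106 CPM, a log2 fold change of -6.26 (SE 0.82). The count was 5750 without race 3 replicate 2, 6723 without noninfected replicate 1 and 6688 without noninfected replicate 3.

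Under race 2 the response of Gm072 was smaller in number. The edgeR test called 116 genes, 113 of them higher and 3 lower. Of the isoflavonoid list 3 of 14 rose and 11 did not pass, and 10 rose when adjusted over the list alone. Chalcone synthase 7 (Glyma.01G228700) rose by 1.49 (SE 0.30, edgeR adjusted p = 0.0493), to 178 ± 85.8 CPM, and the chalcone reductase Glyma.02G307300 by 2.66 (SE 0.54, edgeR adjusted p = 0.0488). G4DT (Glyma.10G295300) reached 42.0 ± 35.5 CPM with a log2 fold change of 2.93 (SE 0.61) and did not pass (edgeR adjusted p = 0.0567). That mean joins unlike libraries, at 44.5, 5.42 and 76.2 CPM in replicates 1, 2 and 3, where noninfected ones held 2.40 to 8.29 CPM and replicate 3 is the library that stood apart. Replicate 2 was also the lowest for chalcone synthase 7, at 83.5 CPM against 201 and 251 CPM. Over 14 alternatives chalcone synthase 7 lost the call in 9 (adjusted p from 0.000192 to 0.606) and the reductase in 10 (2.64e-05 to 0.621), both without any 1 of the 6 libraries except race 2 replicate 2. Camera called the list (adjusted p = 2.90e-07), but not with an estimated correlation (adjusted p = 0.112). Of the pathogenesis-related list 3 of 4 rose, genome-wide and adjusted over the list alone. The PR1 gene Glyma.15G062400 rose by 3.71 (SE 0.49) and the PR10 gene SAM22 (Glyma.07G243500) by 4.33 (SE 0.65), the latter to 237 ± 223 CPM from 203, 32.4 and 474 CPM. SAM22 lost the call in 4 of 14 alternatives (1.89e-12 to 0.542), including without any 1 noninfected library, and Glyma.15G062400 in 2 (7.56e-14 to 0.538), including without noninfected replicate 1. The camera test of the list gave adjusted p = 2.59e-06, and adjusted p = 0.0857 with an estimated correlation. Of the phenylpropanoid list 2 of 11 rose, both ammonia-lyases, Glyma.03G181600 by 1.42 (SE 0.27) and Glyma.03G181700 by 1.58 (SE 0.30), and 4 rose when adjusted over the list alone. These lost the call in 6 (0.000192 to 0.541) and 7 (0.000115 to 0.550) of 14 alternatives, including without race 2 replicate 1 or any 1 noninfected library. Camera did not call this list (adjusted p = 0.123). None of the 8 resistance-locus genes passed, genome-wide or adjusted over the list alone, and camera gave adjusted p = 0.835 for that list.

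The highest-ranked gene in this comparison, Glyma.09G040400, had 27.5 ± 30.3 CPM under race 2 against 0.0264 ± 0.0248 CPM, from 20.2, 1.46 and 60.8 CPM in replicates 1 to 3, and the lowest-ranked, Glyma.02G302600, went from 13.4 ± 1.24 to 4.08 ± 1.26 CPM and fell by 1.72 (SE 0.28). They lost the call in 3 (3.72e-15 to 0.538) and 6 (2.72e-06 to 0.538) of 14 alternatives, both without noninfected replicate 1. The count of 116 rested on single libraries. It was 38, 1253 and 33 without race 2 replicates 1, 2 and 3, and 3, 29 and 15 without noninfected replicates 1, 2 and 3. An edgeR fit of these 6 libraries alone called 0 genes, with 2688 of 38850 tested at an unadjusted p under 0.05, and DESeq2 on all libraries called 887.

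Gm137 infected with race 3 showed the isoflavonoid and pathogenesis-related genes higher as well. Of the isoflavonoid list 12 of 14 rose and 2 did not pass. G4DT (Glyma.10G295300) went from 8.24 ± 1.29 to 301 ± 59.9 CPM, a log2 fold change of 5.19 (SE 0.68, edgeR adjusted p = 8.16e-05). Chalcone synthase 7 (Glyma.01G228700) rose from 116 ± 22.6 to 948 ± 245 CPM, or by 3.03 (SE 0.32), and isoflavone synthase 2 (Glyma.13G173500), which makes the isoflavone skeleton, by 2.00 (SE 0.40). Adjusted over the list alone, 12 rose and 1 fell. The list had a camera adjusted p = 5.58e-09, and adjusted p = 0.0857 with an estimated correlation. Of the phenylpropanoid list 6 of 11 rose, genome-wide and adjusted over the list alone, led by the ammonia-lyase Glyma.03G181700 at 3.26 (SE 0.31). Camera called it (adjusted p = 0.00396), but not with an estimated correlation (adjusted p = 0.296). Of the pathogenesis-related list 3 of 4 rose by either adjustment. The PR1 gene Glyma.15G062400 went from 2.86 ± 0.971 to 269 ± 79.4 CPM, or up by 6.55 (SE 0.56), and the PR10 gene SAM22 (Glyma.07G243500) rose by 5.79 (SE 0.70). In camera the list had adjusted p = 5.98e-05, and adjusted p = 0.0857 with an estimated correlation.

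In the same comparison the rhg1 amino acid transporter (Glyma.18G022400) went from 611 ± 54.3 to 293 ± 60.01 CPM and fell by 1.06 (SE 0.30, edgeR adjusted p = 0.0198), and NSF (Glyma.07G195900) rose by 0.54 (SE 0.15, edgeR adjusted p = 0.0189). The adjusted p reached 0.0909 (without race 3 replicate 2) and 0.0955 (without noninfected replicate 2) over 15 alternatives each. The other 6 resistance-locus genes did not pass, with log2 fold changes of -0.16 (SE 0.17) for the alpha-SNAP gene (Glyma.18G022500) and 0.05 (SE 0.19) for the serine hydroxymethyltransferase (Glyma.08G108900), and camera gave adjusted p = 0.985 for the list. In all, 9045 genes were called, 5296 higher and 3749 lower, and 5486 changed at least 2-fold. Glyma.20G204500 had no reads in noninfected roots and 15.2 ± 9.09 CPM under race 3, at least 1284-fold higher against the floor of 3 reads over the group, or 842-fold without race 3 replicate 2 (25.7 CPM, against 9.45 and 10.5 CPM). Glyma.08G131925 went from 13.1 ± 4.77 to 0.282 ± 0.0998 CPM, a log2 fold change of -5.53 (SE 0.81). The count was 5477 without race 3 replicate 2, 5440 without noninfected replicate 2 and 6013 without noninfected replicate 3.

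Under race 2, Gm137 roots had 4 of 14 isoflavonoid genes higher, 10 not past the test, and 6 higher when adjusted over the list alone. G4DT (Glyma.10G295300) rose to 81.8 ± 20.1 CPM, or by 3.31 (SE 0.62, edgeR adjusted p = 0.00770), a chalcone reductase (Glyma.02G307300) by 2.55 (SE 0.53) and chalcone synthase 7 (Glyma.01G228700) by 1.47 (SE 0.30). These 3 lost the call without noninfected replicate 3, with an adjusted p of 2.92e-05 to 0.0575, 1.65e-05 to 0.0795 and 7.16e-05 to 0.0941 over 15 alternatives. The camera test of the list gave adjusted p = 6.78e-06, and adjusted p = 0.145 with an estimated correlation. Of the phenylpropanoid list 3 of 11 rose and 5 when adjusted over the list alone, with cinnamate 4-hydroxylase Glyma.20G114200 up by 2.50 (SE 0.61) and the ammonia-lyase Glyma.03G181700 by 1.99 (SE 0.30). The hydroxylase lost the call in 6 of 15 alternatives (0.000325 to 0.177), including without race 2 replicate 1 or 2 or any 1 noninfected library. The list had a camera adjusted p = 0.00334, and adjusted p = 0.296 with an estimated correlation. Of the pathogenesis-related list 3 of 4 rose by either adjustment, among them the PR1 gene Glyma.15G062400 by 4.28 (SE 0.51) and the PR10 gene SAM22 (Glyma.07G243500) by 4.16 (SE 0.65). In camera the list had adjusted p = 3.07e-06, and adjusted p = 0.0857 with an estimated correlation. None of the 8 resistance-locus genes passed by either adjustment (camera adjusted p = 0.505).

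The edgeR test called 1131 genes in Gm137 under race 2, 923 higher and 208 lower. Glyma.20G204500, without reads in noninfected roots, had 3.80 ± 4.77 CPM, at least 320-fold higher against the floor of 3 reads over the group. Replicate 1 held 9.28 CPM and the other 2 held 0.651 and 1.45 CPM, the bound was 88.8-fold without replicate 1, and the call was lost in 6 of 15 alternatives (7.06e-07 to 0.213), including without that library. Glyma.04G143500, at 1.03 ± 0.971 CPM in noninfected roots, had no reads and was at least 86.5-fold lower, or 40.2-fold without noninfected replicate 2 (2.14 CPM, against 0.325 and 0.636 CPM). The count was 477 without race 2 replicate 1, and 667, 360 and 396 without noninfected replicates 1, 2 and 3. Without Gm072 race 2 replicate 3, which takes no part in this comparison but enters the shared spread, it was 3645. Among the top 10 raised genes, Glyma.17G178700, Glyma.17G173301 and Glyma.17G206001 were at least 156-, 148- and 102-fold higher against the floor (the last 61.2-fold without race 2 replicate 2). All lacked reads in noninfected Gm137 but had 15.1 ± 4.71, 15.6 ± 6.24 and 10.7 ± 2.50 CPM in noninfected Gm072. A rise with infection and a presence of transcripts of the other line cannot be told apart for them.

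**Figure D2:**
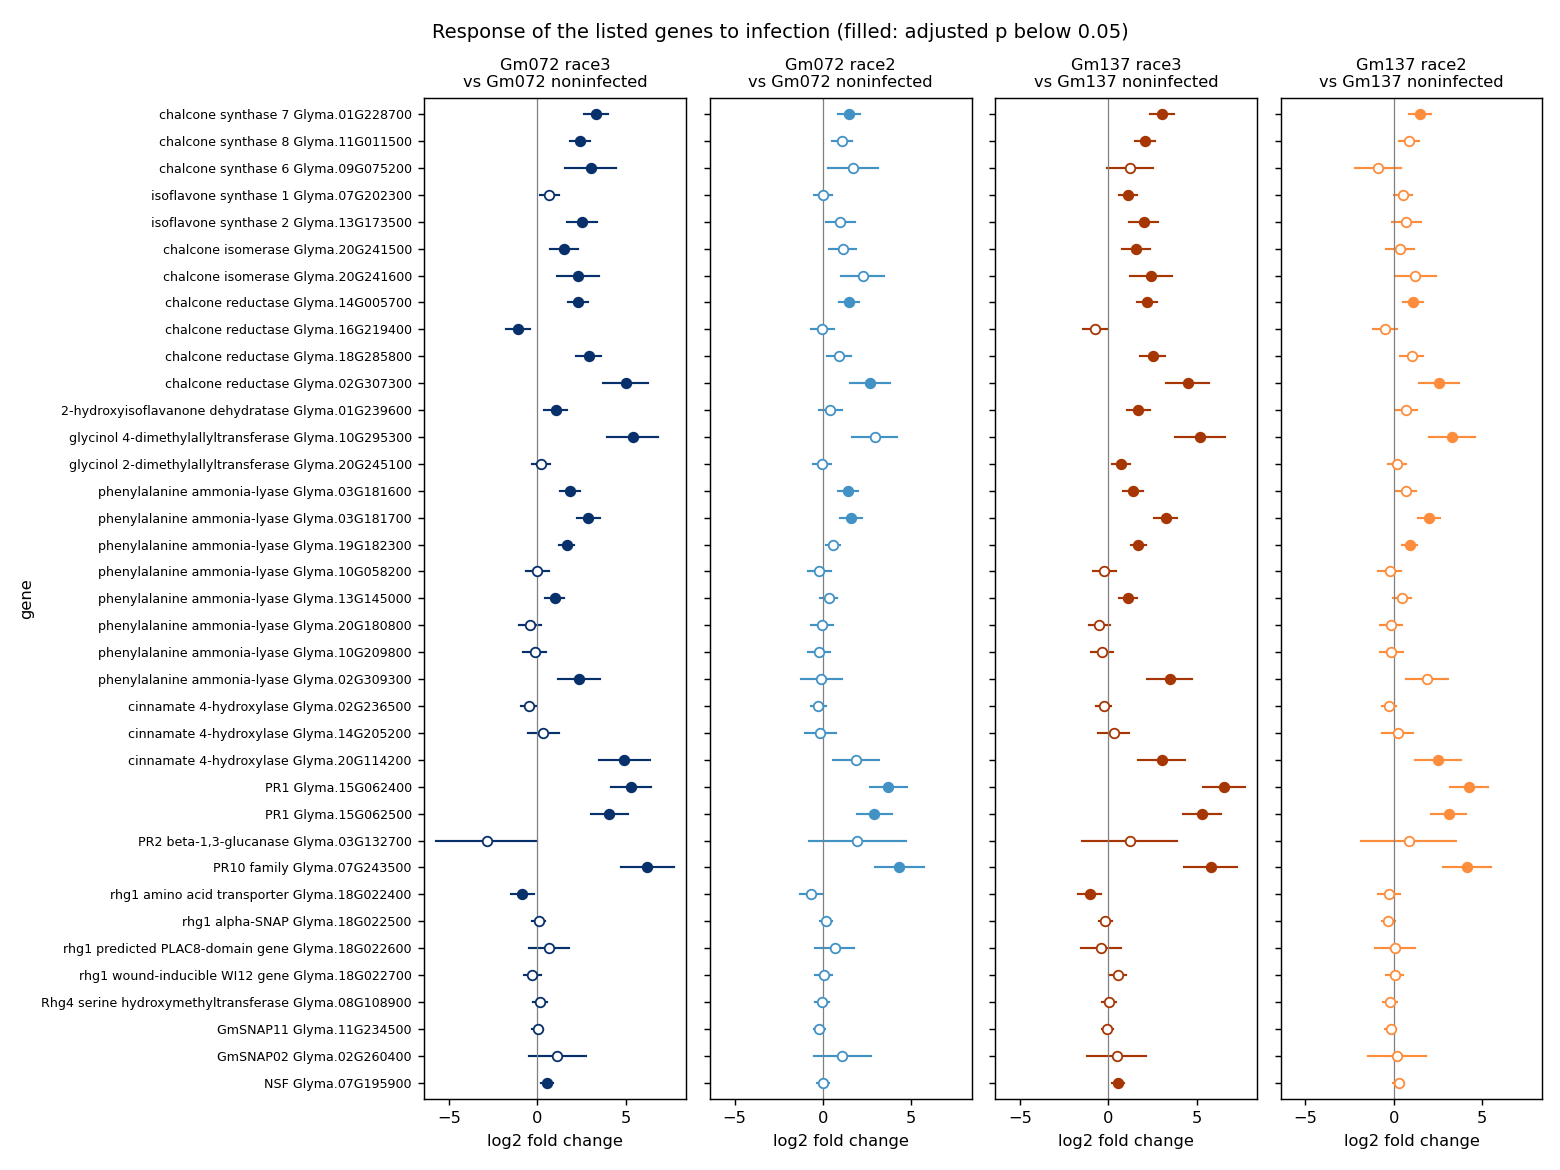
Log2 fold change of each tested list gene (rows) in the 4 infection comparisons (panels), with bars for an approximate 95% confidence interval computed from the SE and filled points for an adjusted p under 0.05. G4DT lies at 5.39 and 5.19 under race 3 and at 2.93 and 3.31 under race 2 in Gm072 and Gm137, while the rhg1 alpha-SNAP gene lies between -0.31 and 0.18 in the 4 panels.

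Race 2 and race 3 were compared directly within each line. In Gm072 the isoflavonoid list had 6 genes lower under race 2 than under race 3, 1 higher and 7 not past the test. G4DT (Glyma.10G295300) differed by -2.46 (SE 0.60, edgeR adjusted p = 0.0154), chalcone synthase 7 (Glyma.01G228700) by -1.83 (SE 0.31) and the chalcone reductase Glyma.18G285800 by -1.98 (SE 0.32). Camera placed the list lower (adjusted p = 7.71e-06), but not with an estimated correlation (adjusted p = 0.275), and 8 were lower and 1 higher when adjusted over the list alone. Of the phenylpropanoid list 4 of 11 were lower, and 5 when adjusted over the list alone (camera adjusted p = 0.00420, and adjusted p = 0.348 with an estimated correlation). Cinnamate 4-hydroxylase Glyma.20G114200 differed by -3.06 (SE 0.63). Of 4 pathogenesis-related genes 2 were lower, with the PR1 gene Glyma.15G062400 at -1.60 (SE 0.45), and the glucanase Glyma.03G132700 differed by 4.81 (SE 1.47), at 436 ± 659 against 15.5 ± 11.4 CPM. Its race 2 libraries held 97.9, 15.04 and 1196 CPM, and without replicate 3 the log2 difference was 1.88 and did not pass. The glucanase lost the call in 8 of 14 alternatives (0.00289 to 0.357), including without any 1 race 3 library, and the PR1 gene in 4 (0.000949 to 0.232), including without race 3 replicate 2 or race 2 replicate 1 or 2. Adjusted over the list alone, 3 were lower and 1 higher, and camera did not call the list (adjusted p = 0.0628). NSF (Glyma.07G195900) was the one resistance-locus gene past the threshold, at -0.52 (SE 0.15, edgeR adjusted p = 0.0361, up to 0.307 over 14 alternatives, and lost without race 3 replicate 1 or 2 or race 2 replicate 2 or 3), by either adjustment (camera adjusted p = 0.743 for the list).

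Over all genes 5267 differed between the races in Gm072, 2903 higher and 2364 lower under race 2, while voom with quality weights called 2897 higher and 3182 lower. Glyma.12G200400 had no reads under race 2 and 10.7 ± 13.9 CPM under race 3, at least 813-fold lower under race 2 against the floor of 3 reads over the group. Race 3 replicate 3 held 26.6 CPM of it and the other 2 held 3.85 and 1.51 CPM, with a bound of 204-fold without replicate 3, and Glyma.13G323800 was higher under race 2 at 1.52 ± 0.877 against 0.0755 ± 0.106 CPM. The count was 1521 without race 3 replicate 2 and 3328 without race 2 replicate 2. An edgeR fit of these 6 libraries alone called 0 genes, with 6373 of 38712 tested at an unadjusted p under 0.05, and DESeq2 on all libraries called 7826.

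In Gm137 the same comparison called 261 genes, 100 higher and 161 lower under race 2. The isoflavonoid list had 3 genes lower and 11 not past the test, with chalcone synthase 7 (Glyma.01G228700) at -1.56 (SE 0.30, edgeR adjusted p = 0.0314, lost in 6 of 15 alternatives, 9.46e-05 to 0.167), and 11 lower when adjusted over the list alone. The camera test of the list gave adjusted p = 8.71e-09, and adjusted p = 0.109 with an estimated correlation. Of the pathogenesis-related list 2 of 4 were lower, the PR1 genes Glyma.15G062400 at -2.27 (SE 0.46) and Glyma.15G062500 at -2.20 (SE 0.44), lost in 5 (8.04e-05 to 0.180) and 4 (0.000114 to 0.175) of 15 alternatives, and 3 when adjusted over the list alone (camera adjusted p = 0.00198, and adjusted p = 0.152 with an estimated correlation). No gene of the phenylpropanoid list passed genome-wide and 5 were lower when adjusted over the list alone (camera adjusted p = 0.0164, and adjusted p = 0.382 with an estimated correlation). None of the 8 resistance-locus genes passed by either adjustment (camera adjusted p = 0.459). Chalcone synthase 7 and both PR1 genes lost the call without race 3 replicate 2 or 3 or race 2 replicate 2 or 3. Glyma.11G224800 stood at 10.1 ± 14.1 under race 2 against 0.399 ± 0.271 CPM, from 1.33, 2.55 and 26.4 CPM in replicates 1 to 3. Without race 2 replicate 3 its log2 difference was 2.28 and did not pass, and 6 of 15 alternatives lost the call (9.35e-07 to 0.172). Glyma.04G114600 had no reads under race 2 and 0.428 ± 0.453 CPM under race 3, at least 35.8-fold lower against the floor of 3 reads over the group, or 14.8-fold without race 3 replicate 1 (0.931 CPM, against 0.2996 and 0.0531 CPM). Its call was lost without race 2 replicate 2 or 3 (7.36e-06 to 0.0985 over 14 alternatives).

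The count of 261 rested on single libraries. It was 102, 38 and 11 without race 3 replicates 1, 2 and 3, and 515, 1 and 4 without race 2 replicates 1, 2 and 3. The majority of lower genes was lost without race 3 replicate 3 (7 higher, 4 lower), race 2 replicate 1 (268 and 247), race 2 replicate 2 (1 and 0) and race 2 replicate 3 (2 and 2). Without Gm072 race 2 replicate 3, which takes no part in it, the count was 3519.

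**Figure D3:**
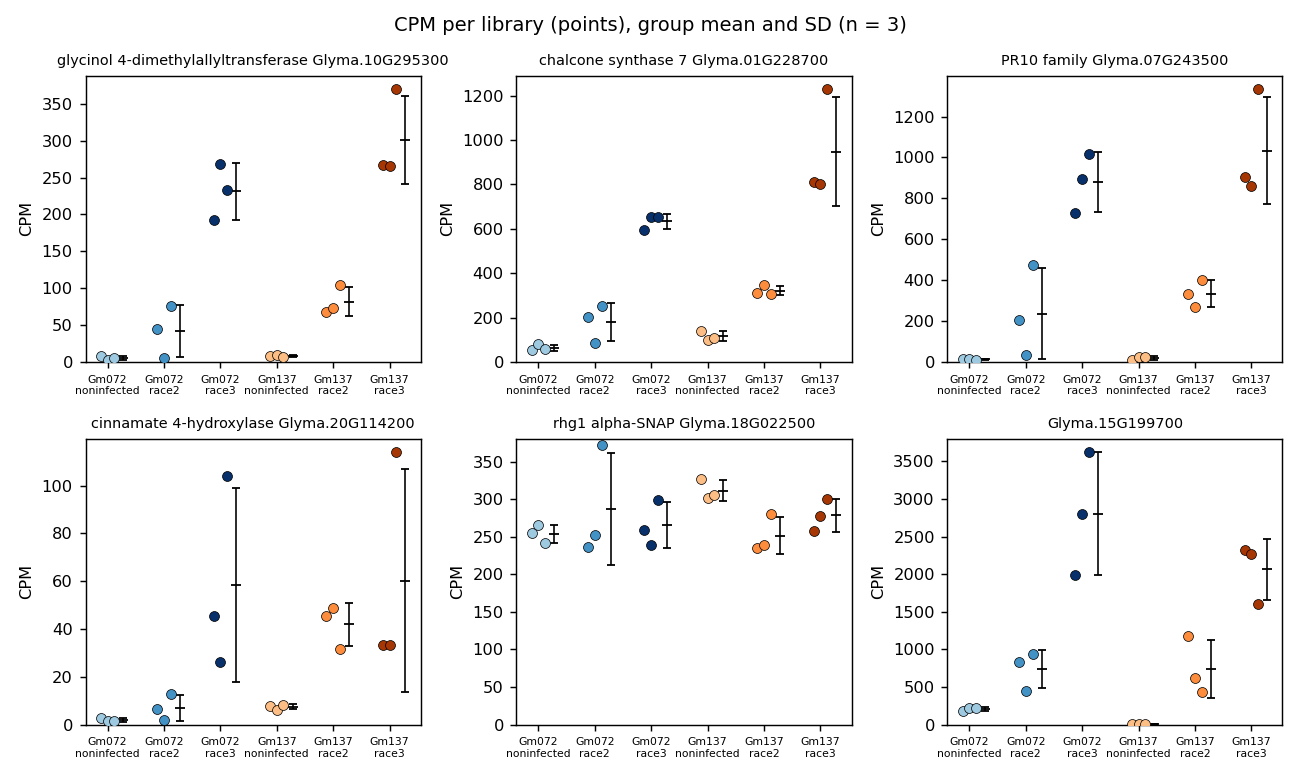
CPM of 6 genes in each library (points, linear axis from 0) by group, with the group mean and SD (n = 3) beside the points. Under race 3, G4DT averages 231 and 301 CPM in Gm072 and Gm137 and SAM22 averages 880 and 1033 CPM, the alpha-SNAP gene stays between 251 and 311 CPM on average in the 6 groups, and Glyma.15G199700 averages 209 CPM in noninfected Gm072 and 9.79 CPM in noninfected Gm137.

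Most genes called under race 2 were also called under race 3. In Gm072 all 113 raised and all 3 lowered genes of the race 2 comparison were called in the same direction under race 3, where independent lists would share 15.4 and 0.339. In Gm137, 901 raised and 196 lowered genes were shared, where independent lists would share 118 and 18.9. Within a line both comparisons use the same controls, so draws with no effect were simulated 100 times. Across 30763 genes with a mean log2 CPM of at least 1, the log2 fold changes under both races correlated at 0.687 in Gm072 and 0.848 in Gm137, against 0.499 and 0.498 in the draws. The covariance was 0.308 and 0.479 against simulated values of 0.0470 and 0.0467. The same sign was seen in 68.8% of genes in Gm072, against 66.7% on average and at most 67.3% in the draws, and in 75.9% in Gm137, against 66.6% and at most 67.3%. Without Gm072 race 2 replicate 1 the Gm072 values were a correlation of 0.505, a covariance of 0.253 and 62.0%, and without replicate 3 they were 0.742, 0.291 and 73.9%. Without replicate 1 the correlation lay within the range of the Gm072 draws (0.480 to 0.526) and the same-sign share below their mean. The covariance stayed above their highest value of 0.0510. The draws had 3 libraries per group and varied each gene on its own, so their range leaves out shifts shared by many genes. The raised genes shared in Gm072 were 35, 952 and 33 without race 2 replicates 1, 2 and 3, 70 and 74 without race 3 replicates 1 and 2, and 3, 28 and 14 without noninfected replicates 1, 2 and 3. In Gm137 they were 444 without race 2 replicate 1, and 581, 318 and 356 without noninfected replicates 1, 2 and 3. The lowered ones there were 24, 120, 74, 36 and 31 without race 2 replicates 1 and 3 and noninfected replicates 1, 2 and 3. In Gm072 the shared lowered genes were 70 without race 2 replicate 2 and 6 without race 3 replicate 3. They were 0 without race 2 replicate 1 or 3 or noninfected replicate 1. Splitting 3 control libraries leaves fewer than 2 in a part, so part of the excess may come from the shared controls. Genes are not independent replicates, and these correlations are across genes.

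Between the lines, which share no libraries, 3817 raised and 2625 lowered genes were called under race 3 in both, against 721 and 424 for independent lists, and 5 were called in opposite directions. Across genes the race 3 responses of the lines correlated at 0.852. Under race 2 both lines shared 90 raised and 1 lowered gene, against 2.52 and 0.0151 for independent lists, and the correlation was 0.335. The log2 fold changes had the same sign in 45.5% of genes under race 2 and in 83.4% under race 3. Single libraries moved the race 2 values. Without Gm072 race 2 replicate 3, which stood apart, the correlation was 0.517 and the same sign was seen in 60.6%, and without replicate 1 they were 0.134 and 39.8%. The number of raised genes shared under race 2 was 27, 333 and 29 without Gm072 race 2 replicates 1, 2 and 3, 3, 25 and 14 without Gm072 noninfected replicates 1, 2 and 3, 53, 53 and 57 without Gm137 race 2 replicates 1, 2 and 3, and 45, 39 and 42 without Gm137 noninfected replicates 1, 2 and 3. Under race 3 the shared lowered genes were 1712 without Gm072 race 3 replicate 2, 1673 and 1459 without Gm137 race 3 replicates 1 and 2, and 1639 without Gm137 noninfected replicate 2.

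The noninfected lines were compared for differences that precede infection. The edgeR test called 343 genes, 167 higher and 176 lower in Gm137. Several of the top-ranked genes had reads in one line and none in the other. Glyma.08G261500 had 6.09 ± 0.781 CPM in Gm137 and no reads in Gm072, at least 521-fold higher, and Glyma.17G173301 had 15.6 ± 6.24 CPM in Gm072 and no reads in Gm137, at least 1315-fold lower, both against the floor of 3 reads over the group. Read counts alone do not separate a transcript that a line lacks from one whose reads do not align. Among the resistance loci 1 of 8 passed by either adjustment. NSF (Glyma.07G195900) stood at 45.6 ± 4.79 CPM in Gm137 and 85.0 ± 5.58 CPM in Gm072, a log2 fold change of -0.90 (SE 0.15, edgeR adjusted p = 0.00779, and 0.0607 without Gm137 noninfected replicate 2). The alpha-SNAP gene (Glyma.18G022500) differed by 0.29 (SE 0.17, edgeR adjusted p = 0.517) and the serine hydroxymethyltransferase (Glyma.08G108900) by 0.38 (SE 0.19, edgeR adjusted p = 0.440). The list had a camera adjusted p = 0.530 for that list.

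No gene of the isoflavonoid, phenylpropanoid or pathogenesis-related lists passed between the noninfected lines. Adjusted over the list alone, 1, 2 and 0 were higher in Gm137. Camera placed the isoflavonoid list higher in Gm137 (adjusted p = 0.0265), but not with an estimated correlation (adjusted p = 0.532), and gave adjusted p = 0.0870 and 0.574 for the other 2. The count of 343 fell to 199, 211 and 167 without Gm072 noninfected replicates 1, 2 and 3, and to 179 and 172 without Gm137 noninfected replicates 2 and 3. In these last 2 fits more genes were higher than lower (96 and 83, 98 and 74), as with no filter beyond 1 read (171 and 161). Without Gm072 race 2 replicate 3 it was 1855.

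The last comparison asked whether the response to a race differed between the lines. Under race 3 the edgeR test of the difference called 1 gene, Glyma.15G199700, whose response was larger in Gm137 by 3.97 on the log2 scale (SE 0.49, adjusted p = 0.0136). It went from 9.79 ± 1.30 to 2064 ± 401 CPM in Gm137 and from 209 ± 26.3 to 2805 ± 817 CPM in Gm072. Under race 2 the test called 6 genes, 5 with a positive and 1 with a negative difference (Gm137 minus Gm072). Glyma.15G199700 was among them at 4.42 (SE 0.49, adjusted p = 0.00345), with 744 ± 387 CPM in Gm137 and 740 ± 256 CPM in Gm072. The tests for both races use the same noninfected libraries, so its calls are not separate evidence. Glyma.18G080400 differed by 7.59 (SE 1.08, adjusted p = 0.0339), going from 0.0361 ± 0.0625 to 7.09 ± 2.28 CPM in Gm137 and from 8.30 ± 6.58 to 9.03 ± 2.13 CPM in Gm072. Over 20 alternatives each, the former kept the call under race 2 (adjusted p up to 0.0354) and the latter lost it in 10 (2.48e-07 to 0.167). Under race 3 the call of Glyma.15G199700 was lost in 7 of 21 (5.97e-13 to 0.121).

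None of the 37 tested list genes passed in either test of the line difference, genome-wide or adjusted over the list alone. The difference under race 3 was -0.20 (SE 0.81) for G4DT (Glyma.10G295300) and -0.23 (SE 0.24) for the alpha-SNAP gene (Glyma.18G022500), and camera adjusted p-values were between 0.0900 and 0.677 under race 3 and between 0.639 and 0.778 under race 2. At an unadjusted p under 0.05 there were 2068 genes under race 3 and 6302 under race 2. With no difference a share of 0.05 of the 41319 tested genes is expected there. The race 3 count lay at that share and the race 2 count above it. This does not show that the lines respond alike to race 3. On simulated counts the test of that difference recovered 3% of 2-fold changes, and the spread is shared by all libraries. The race 2 test uses Gm072 race 2 replicate 3, the library that stood apart. DESeq2 called 135 and 337 genes. Under race 3 no gene was called without Gm072 race 3 replicate 1 or 2, Gm072 noninfected replicate 2, Gm137 race 3 replicate 1 or 2, or Gm137 noninfected replicate 2 or 3, 33 without Gm137 noninfected replicate 1, 3 without Gm072 noninfected replicate 3 and 8 without Gm072 race 2 replicate 3. Under race 2 the count was 139 without Gm072 race 2 replicate 1 (57 positive and 82 negative differences), 14 without Gm137 noninfected replicate 1, and between 1 and 3 without any of the other 10 libraries.

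**Figure D4:**
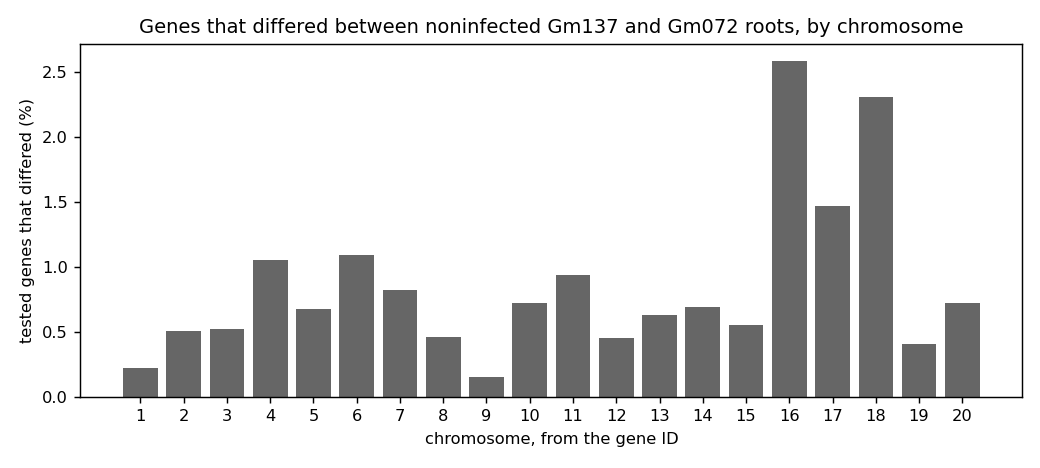
Share of tested genes that differed between the noninfected lines (vertical axis, percent, edgeR adjusted p under 0.05) for each of the 20 chromosomes named in the gene IDs (horizontal axis). The share was 2.58% on chromosome 16 and 2.30% on chromosome 18, and 0.151% on chromosome 9.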

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

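The tests of the library that stood apart, and the counts of other groupings of the libraries, were chosen after the results were seen.

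Glyma.15G199700 responded differently in the lines to both races in edgeR's test of the difference. The log2 difference (Gm137 minus Gm072) was 3.97 (SE 0.49, adjusted p = 0.0136) under race 3 and 4.42 (SE 0.49, adjusted p = 0.00345) under race 2. Both tests use the same noninfected libraries, so these calls are not separate evidence. The noninfected level of this gene was 9.79 ± 1.30 CPM in Gm137 and 209 ± 26.3 CPM in Gm072. Its infected levels were closer, at 2064 ± 401 and 2805 ± 817 CPM under race 3 and 744 ± 387 and 740 ± 256 CPM under race 2. Under race 2 the difference was 7.59 (SE 1.08, adjusted p = 0.0339) for Glyma.18G080400, 4.03 (SE 0.62, adjusted p = 0.0483) for Glyma.11G062700, 2.41 (SE 0.35, adjusted p = 0.0339) for Glyma.19G231800 and 2.25 (SE 0.33, adjusted p = 0.0360) for Glyma.04G185400. Each of these genes also had a lower noninfected mean in Gm137 than in Gm072. It was 0.344 ± 0.268 against 2.80 ± 0.369 CPM for Glyma.11G062700 and 0.551 ± 0.0206 against 1.98 ± 0.335 CPM for Glyma.19G231800. The log2 differences thus reflect starting levels as well as infected ones. For Glyma.04G143500 the fit gave -9.92 (SE 1.47, adjusted p = 0.0483). That gene had no reads in Gm137 under race 2 against 1.03 ± 0.971 CPM without infection, at least 86.5-fold lower against the floor of 3 reads over the group (40.2-fold without noninfected replicate 2), and lost the call in 15 of 20 alternatives (4.47e-07 to 0.230). Glyma.18G080400 lost it in 10 (2.48e-07 to 0.167), Glyma.11G062700 in 14 (2.48e-07 to 0.218), Glyma.19G231800 in 10 (1.37e-06 to 0.152) and Glyma.04G185400 in 12 (1.37e-06 to 0.145). Without any 1 Gm137 race 2 library, or without Gm137 noninfected replicate 2 or 3, each of these 5 genes lost the call.

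Other groupings of the 12 libraries of each line difference were fitted, 100 of them including the real one. For race 3, 3 of the 100 gave as many genes as the real 13, and the highest other gave 4509. It kept the Gm137 groups and exchanged 2 of 3 infected Gm072 libraries with noninfected ones, so it held the infection response of Gm137, and the other groupings also mix or exchange infected and noninfected libraries. For race 2, 6 of the 100 gave as many as the real 3, with a highest other of 72 that was exchanged in the same way. Such groupings do not stand for lines that respond alike, so neither count says whether chance can be excluded.

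In the rows of the table outside the genes, Gm072 race 2 replicate 3 held more reads than any noninfected library. Reads assigned to more than 1 gene made up 1.20% of its table total against at most 0.974%, and reads without a unique alignment made up 7.11% against at most 5.34%.

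The same library stood apart from the other 17 in its genes. It had 997 genes far under the lowest other library (below that level divided by 3), where no other library had more than 177, and 48 genes at 0 that were above 1 CPM in each other library. Lower depth was argued against by its total of 90.1 M reads, above the median of 77.95 M of the others. A mixture with Gm137 was argued against by transcripts of noninfected Gm137 that stood at under 2% of that level in noninfected Gm072 roots, at a median of 0% of their Gm137 level, while the opposite kind stood at 59.2%, although its score on the component that separated the lines, -22.8, lay next to the Gm137 range. The response seen under race 3, as a source of the low genes, was argued against by 1959 genes low here against the noninfected and other race 2 Gm072 libraries. Their median race 3 log2 fold changes were -0.10 in Gm072 (quartiles -0.63 and 0.34) and 0.15 in Gm137 (quartiles -0.37 and 0.65). Genes high in this library took no part in that test, so it does not speak to a stronger rise of infection genes here. Another stage of infection, or a difference in RNA quality, handling or alignment, may remain and was not tested. The test of a mixture covers Gm137 only and does not speak to other genotypes.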

How the results depend on the processing

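Leaving out Gm072 race 2 replicate 3 where it takes no part was chosen after seeing the data. Of 2525 alternative fits of 163 named values, 2230 kept the side of the threshold. Of the rest, 291 kept direction but lost the call, 4 gained it and 0 reversed. The 4 were gained with voom weights. A change of sign counted as reversed only where the main or the alternative fit called the gene. The named values include every resistance-locus gene in each contrast, most of them not called, so sign changes among these stay within the 2230. The cause of the moves below was not tested, except that a fold threshold added to the same test can only lower a count.

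With at least 2-fold change, 6061, 5486 and 2985 genes were called in Gm072 race 3, Gm137 race 3 and Gm072 race 2 against race 3. With voom quality weights the counts were 18536 (Gm072 race 3), 16888 (Gm137 race 3), 5891 (Gm137 race 2), 6619 (Gm137 race 2 against race 3), 6237 (noninfected lines), and 53 and 1 (line difference under race 3 and race 2). With only the groups compared in the fit they were 0 (Gm072 race 2, and Gm072 race 2 against race 3), 14191 (Gm137 race 3), 2696 (Gm137 race 2), 1497 (Gm137 race 2 against race 3), 4468 (noninfected lines), and 13 and 3 (line differences). DESeq2 gave 887 (Gm072 race 2), 2568 (Gm137 race 2), 2466 (Gm137 race 2 against race 3), 1180 (noninfected lines), and 135 and 337 (line differences). The higher share in Gm137 under race 2 went from 81.6% to 57.2% with voom weights.

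Over all pairs of groups replicate numbers showed little pairing: 8 of 45 same-number correlations were above 0.1, with a median of 0.00795. Between the race 3 groups of the lines, however, they were 0.0290, 0.184 and 0.252, the last being the highest of the 45. There each Gm072 library correlated best with the Gm137 library of its own number, so a batch shared by replicate number cannot be excluded. With the number as a block, 50 genes were called in Gm072 race 2, 127 in Gm137 race 2 against race 3 and 1 in the line difference under race 2, and the pathogenesis-related list in Gm072 race 2 against race 3 passed (adjusted p = 0.0382).

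With an estimated correlation in camera, calls were lost at adjusted p of 0.0857 (isoflavonoid list under race 3 in both lines, pathogenesis-related list in Gm072 race 2 and both Gm137 infections), 0.112 (isoflavonoid, Gm072 race 2), 0.145 (isoflavonoid, Gm137 race 2, and pathogenesis-related, Gm072 race 3) and 0.296 (phenylpropanoid, both race 3 comparisons and Gm137 race 2). Between races they were lost at 0.275 and 0.348 (isoflavonoid and phenylpropanoid, Gm072), and 0.109, 0.382 and 0.152 (isoflavonoid, phenylpropanoid and pathogenesis-related, Gm137), and between noninfected lines at 0.532 (isoflavonoid). In the infection contrasts fry gave adjusted p of 6.36e-05 to 0.0195 for the isoflavonoid and 6.36e-05 to 0.00288 for the pathogenesis-related list. For the phenylpropanoid list fry gave adjusted p of 0.00827 and 0.00564 under race 3 and 0.491 and 0.0664 under race 2, in Gm072 and Gm137. The resistance-locus list did not pass in fry (adjusted p of 0.225 to 0.853).

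Leaving out 1 library gave 5750 to 13972 genes for Gm072 race 3, 3 to 1253 for Gm072 race 2, 5440 to 12816 for Gm137 race 3, 360 to 3645 for Gm137 race 2, 1521 to 7602 and 1 to 3519 for race 2 against race 3 in Gm072 and Gm137, 167 to 1855 for the noninfected lines, and 0 to 33 and 1 to 139 for the line differences under race 3 and race 2. The highest values for Gm072 race 3, Gm137 race 3, Gm137 race 2, Gm137 race 2 against race 3 and the noninfected lines came without Gm072 race 2 replicate 3.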

Other observations

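The tests below of transcripts of the other line and of the smaller race 2 counts, and the counts of other groupings, were chosen after the results were seen.

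Genes that differed between the noninfected lines lay close together. Of 341 placed on a chromosome, 137 had another within 10 tested genes, against a median of 52 and at most 86 in 10000 permutations (p = 0.0001, the smallest they can give). Chromosome 18 held 47, chromosome 16 held 41 and chromosome 17 held 30. Of the 6 genes of the line differences, Glyma.15G199700 had the highest level, at 2805 ± 817 CPM in Gm072 and 2064 ± 401 CPM in Gm137 under race 3.

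Some transcripts seen in noninfected roots of 1 line and at under 2% of that level in each noninfected library of the other, a limit that the choice of transcripts sets, had reads in infected roots of that other line. Of 18 Gm072 and 36 Gm137 transcripts below that limit, 10 and 25 also kept a set share of their level in each infected library of their own line and were used. Of these 10 Gm072 transcripts 8 lay on chromosome 17. Their medians were 2.40%, 15.01% and 11.74% of the Gm072 level in the Gm137 race 2 libraries and 0.305%, 0% and 5.25% in the race 3 libraries. Glyma.18G080400, also among the 10, stood at 60.3% to 146% in the infected Gm137 libraries, and Glyma.16G174900 at 0% to 52.7%. For one share of RNA of the other line per library, 3 of the 4 infected Gm072 libraries with enough expected reads had at least 3 Gm137 transcripts below the limit. The limit assumes a share from the upper quartile and levels of noninfected Gm137, and the fourth library had 2 below it, so this source cannot be told apart from others. Genome segments of the other line in some plants may add to it: shares of neighbouring transcripts correlated at 0.302 against 0.0904 for all pairs (permutation p = 0.0219). Neighbouring copies that share reads or regulation could give the same, and the labels do not say whether plants were pooled.

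Fewer genes were called under race 2 than under race 3 in both lines. Lower depth was argued against by a median of 83.7 M reads in race 2 libraries and 73.2 M in race 3 libraries. Larger spread with responses of equal size was argued against by slopes of the race 2 on the race 3 response of 0.391 in Gm072 and 0.548 in Gm137, with genes chosen and weighted by the race 3 response of the other line (at most 0.463 and 0.614 without 1 race 2 library). Genes chosen in the same line gave 0.390 and 0.607. A smaller response to race 2, or an earlier stage of it, may remain, and the labels give no time point. The slopes do not exclude that a larger spread adds to either. The counts do not measure how far each root was infected, so the slopes cannot separate race from level of infection.

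Each comparison of 3 against 3 libraries has 10 groupings, too few for a share under 0.05. In fits of the groups compared, the real grouping and the highest other gave 11149 and 0 genes for Gm072 race 3, 14191 and 0 for Gm137 race 3, 2696 and 1 for Gm137 race 2, 1497 and 0 for Gm137 race 2 against race 3, and 4468 and 5 for the noninfected lines, with 1 grouping of 10 as large as the real one in each. For Gm072 race 2, and for Gm072 race 2 against race 3, the real and the highest other count were 0 and 0, so 10 of 10 were as large.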
